A study of Saccharomyces cerevisiae with 1245 samples.

How the data were processed

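Chromatin from yeast grown in culture and crosslinked with formaldehyde was profiled by ChIP-exo, and 20 samples of histones and histone marks by MNase-ChIP-seq, per the labels. Reads were processed with BWA, Picard and SAMtools on the sacCer3 build, per the submitters' processing notes, which give no versions. Each deposited list holds the peaks of 1 library, as 1 bp positions with the name ChExMix in a column of its own, per the file contents. The deposited peak score is a whole number from 66 to 1000. The authors' definition of the score is not stated in the labels, and 23.8% of peaks have the highest value, so scores were used only to rank peaks within a library. Per the labels' protocols no control or input was named for the lists, so what was subtracted is not known.

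Positions were taken as 1-based. Genes came from the R64 annotation of the same assembly, with 6002 protein-coding nuclear genes, 275 tRNA genes and 12 rRNA genes. As a check of the build, 87.5% of the peaks of RNA polymerase III, TFIIIB and TFIIIC lay within 250 bp of a tRNA gene, which make up 1.30% of the annotated length, and 275 of 275 tRNA genes had such a peak. Genome sequence, centromeres, replication origins and chromosome lengths were not used here, so the motif comparison was not run. The end of a chromosome was taken as the larger of the last annotated gene end and the last peak.

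Targets were placed by name, before the data were examined, into 18 classes and into complexes, and gene lists and known regulator targets were fixed then too, as were the tests and most alternatives. Those choices were made before the peak lists were opened; the sizes of some lists' files had been seen. The added alternatives for heat shock, with libraries of the same library-number series (title numbers in the same block of 1000) without Rsc9, and with chaperone promoters as a share of all promoters with a peak, were chosen after seeing the data. The comparison of RNA polymerase I machinery with random targets among the 20 nearest in peak number was too, and so was keeping 1 gene of each divergent pair whose promoter windows overlap (1402 pairs). So were the tests of SAGA against RSC. Details that the fixed plan left open were also settled with the lists in hand: a target's tested value is the mean of log10 peak number over its libraries, cofactors were pooled, the 2 Hsf1 antibodies were averaged, and a place counted as shared was a 100 bp bin.

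The main comparisons used ChIP-exo libraries without heat shock. Comparisons of places needed at least 20 peaks per library, which 794 libraries had and 321 did not. The 89 samples without a list, among them all 15 untagged samples, were left out and not counted as 0. The sample whose labels name 2 targets entered no group.

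Peaks of 2 libraries matched when within 100 bp. The replicate overlap is the share of the smaller list's peaks with a match, set against 100000 random pairings of libraries of like peak number. The overlap score of a complex divides the matched peaks of the smaller list by the geometric mean of the list sizes, and was set against 100000 random sets matched on peak number, which were free to hold members of the same complex. Features were assigned in a fixed order: rRNA gene, within 250 bp of a tRNA gene, within 10000 bp of a chromosome end, promoter (up to 500 bp upstream of a coding start, outside coding sequence), the parts of coding genes, and other intergenic sequence. Positions used peaks within 1000 bp of a coding start. A promoter was bound when at least 1 library of a target had a peak from 700 bp upstream to 100 bp downstream of the coding start.

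Classes were compared by two-sided permutation tests across targets with 100000 resamples, and gene lists across promoters in the same way. Regulators and targets at ribosomal protein promoters were tested by Fisher's exact test, one-sided, and cofactors by Fisher's exact test, two-sided. Heat shock and native antibodies were tested by exact sign-flip permutation tests over targets. Families were adjusted by Benjamini-Hochberg at 0.05. The rule used for libraries that stand apart from their group takes at least 4 libraries, which no group had, so it was not run.

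Named targets are the 3 with the most peaks in each class, the best pair of each complex that passed, the 15 promoters with the most targets, the 10 targets with the smallest adjusted p at ribosomal protein promoters, the 20 regulators past the threshold with the largest share of known targets, and the 10 chaperone promoters with the largest difference in share with heat shock. The text gives a selection of these and a summary of the rest. Other targets named beside a count, such as Msn2, Spt3, Rsc9 and those at kinetochore or origin places, were chosen after their values were seen.

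Alternatives changed the match distance (50 and 250 bp), the least peak number (5 and 50), the promoter window (300 and 1000 bp upstream), the antibodies, replicates and classes used, the reference for peak number and position, and the places left out. The statistics were also tested on simulated peaks, after they had first been run on the lists. In that test the peak number comparison recovered 95.0% of 40 shifted classes, and 5.63% of 160 unshifted classes fell under an unadjusted 0.05. The complex test recovered 10 of 10 planted sets and called 0 of 10 others, and the regulator test recovered 40 of 40 planted regulators and called 0 of 40 others. Peaks that were not planted lay at random places, and random pairings of simulated libraries overlapped by 0% in the median, against 14.9% in the lists. The simulation therefore does not show how these tests behave with places shared by many targets. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with plots by matplotlib 3.10.9.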

Results

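The data are ChIP-exo peak lists from budding yeast. ChIP-exo is chromatin immunoprecipitation in which an exonuclease trims the recovered DNA up to the crosslinked protein, so a peak is a single position. The series holds 1245 samples of 793 targets: 1224 ChIP-exo samples, 20 MNase-ChIP-seq samples of histones and histone marks, and 1 sample whose labels name 2 different targets. Most samples, 1121, carry a TAP tag, 45 carry an HA tag and 23 were made with antibodies from the Weil Lab. A heat shock is given for 22 samples, 20 at 6 min and 2 at 3 min. Peak lists were analysed for 1156 samples. The main comparisons used 1115 ChIP-exo libraries without heat shock, covering 716 targets and 360480 peaks. These libraries form 738 groups of the same target, antibody and condition, of which 364 have 1 library, 371 have 2 and 3 have 3. List sizes over all samples ran from 1 to 7062 peaks, with a median of 84 and quartiles of 17 and 369.25. Read depth is unknown from the lists, so a place without a peak is not shown to be unbound. Nothing in the labels says that replicates are separate cultures, so the p-values may reflect technical spread.

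Proteins of the transcription machinery had the most peaks. Sua7, the yeast TFIIB that places RNA polymerase II at promoters, had 6259 ± 733 peaks (SD, n = 3), the highest mean of all targets. Tfb4 of TFIIH had 4416 ± 166 (SD, n = 2) and Tfa2 of TFIIE had 4030 ± 1853 (SD, n = 2). Rpb3, a core subunit of RNA polymerase II, had 2437 ± 106 (SD, n = 2), and the elongation factors Spt6 and Spt5 had 2253 ± 578 and 2206 ± 601 (SD, n = 2 each). The largest mean outside the transcription classes was that of Htz1, the histone variant H2A.Z, with 3653 ± 2677 (SD, n = 2).

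The question was which kinds of protein have more peaks than metabolic enzymes. The 36 metabolic enzymes with a list, classed by name, served as the background, because the 15 untagged samples have no list here. Whether some of these enzymes have a role on chromatin was not tested. Enzymes had a median of 9.5 peaks per target, from 1 to 511.5 for Lys20, an enzyme of lysine synthesis. Another 15 of the 51 enzymes in the series have no list, and whether that means no peak is not known, so the median and the folds hold for enzymes with a list. On the log scale, RNA polymerase II subunits had 155-fold more peaks than enzymes (7 targets), general transcription factors 60.8-fold more (34 targets) and elongation factors 53.5-fold more (23 targets). RNA processing and termination factors had 31.0-fold more (24 targets), RNA polymerase III machinery 23.3-fold more (21 targets), SAGA, a histone-acetylating coactivator, 17.1-fold more (13 targets), and Mediator, which links activators to the polymerase, 11.3-fold more (24 targets). Sequence-specific factors had 6.83-fold more peaks (138 targets, of which 121 lay above the enzyme median), led by Fhl1 with 1018 ± 107 and the general regulatory factor Reb1 with 1001 ± 199 (SD, n = 2 each). Of 17 classes, 16 passed the two-sided permutation test with Benjamini-Hochberg adjustment. RNA polymerase I machinery did not (1.45-fold, 14 targets, adjusted p = 0.377). No list had a peak in the large rRNA genes that RNA polymerase I transcribes, so its peak number cannot count those genes. Its peak number therefore does not show how much of it lies on chromatin, in this or the next comparison. These calls rest on the enzymes: only 4 of the 36 have a library beyond replicate 1, and no class passed against those 4 when replicate 1 was left out. Against all other targets in place of the enzymes, 7 classes were higher and 3 lower. The 3 lower were enzymes, other proteins and RNA polymerase I machinery (adjusted p = 0.0153), while Mediator (adjusted p = 0.0701) and sequence-specific factors (adjusted p = 0.120) were not called there.

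**Figure D1:**
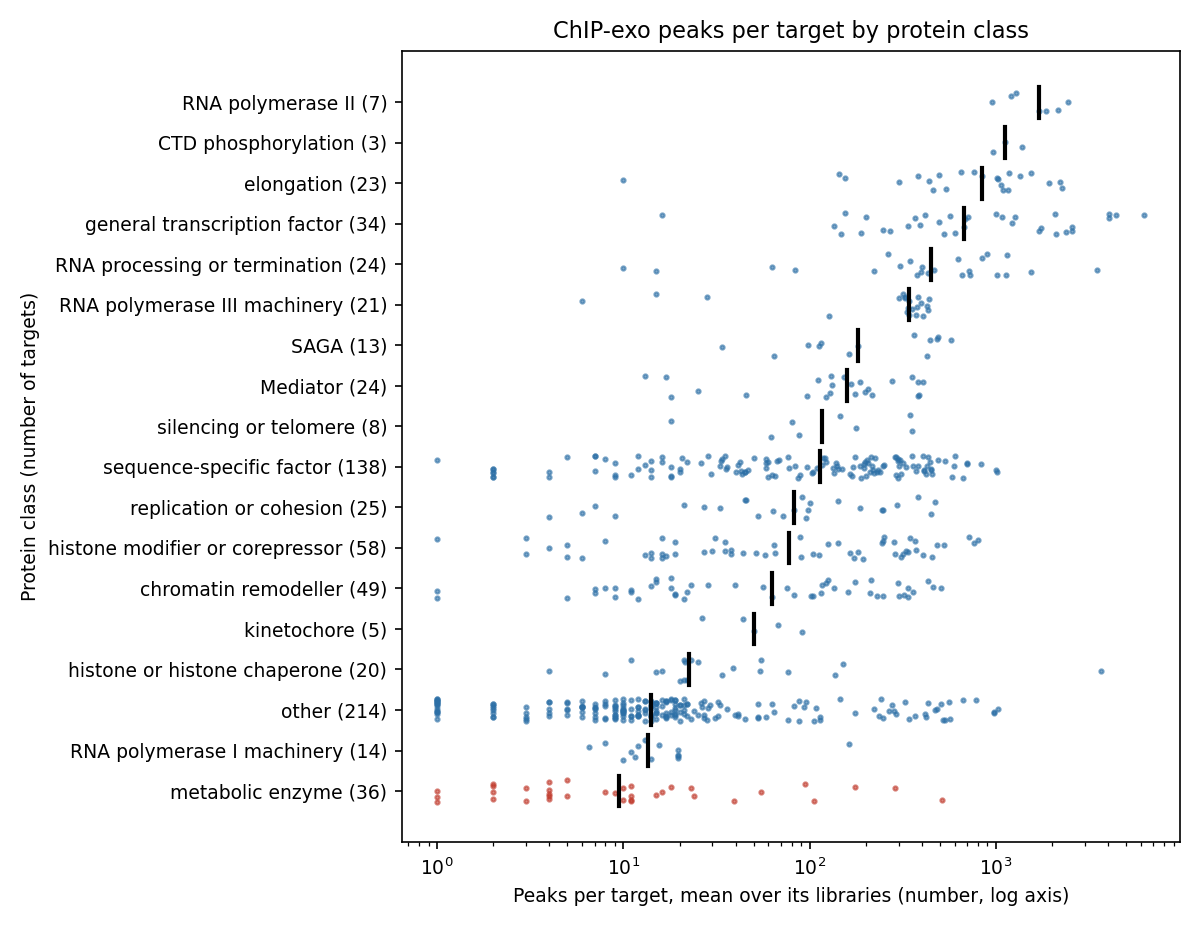
Peaks per target (mean over its libraries, log axis) for each protein class, with the number of targets in brackets. Each point is 1 target and each black bar is the class median; metabolic enzymes, in red, have a median of 9.5 and RNA polymerase II subunits a median of 1695.

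How well a list repeats was asked with pairs of libraries of the same target and antibody. In the median of 307 groups, 76.6% of the smaller list's peaks lay within 100 bp of a peak of the other list (quartiles 62.6% and 90.3%). Random pairings of libraries with similar peak numbers gave 14.9%, and 303 of the 307 groups lay above that value (permutation p = 1e-05, one-sided, the smallest that 100000 permutations can give). RNA polymerase III machinery repeated best, with a mean of 97.1% ± 7.42 (SD, n = 18 groups), against 72.1% in all other groups. General transcription factors had 89.1% ± 10.5 (SD, n = 28). Chromatin remodellers, which move or exchange nucleosomes, had 55% ± 25.4 (SD, n = 23), against 75.1% in the other groups. These 3 classes passed the two-sided permutation test (adjusted p = 0.000170, 0.000227 and 0.000170), and 5 classes did with a 50 bp match or with lists of at least 5 peaks. With a 250 bp match 2 classes did, and general transcription factors were not among them.

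Several classes differed from the other targets in where their peaks lay. RNA polymerase III machinery, which transcribes tRNA genes, had 82.2% ± 20.7 of its peaks at tRNA genes (SD, n = 19 targets), against 4.75% for all other targets and 1.30% of the annotated length. General transcription factors had 69.1% ± 14.7 of their peaks in promoters (SD, n = 33), against 24.4%. Elongation factors had 7.39% ± 9.68 in promoters and 31.7% ± 8.57 in the part of genes farthest from the coding start, with genes split into 3 equal parts (SD, n = 22), where the other targets had 18.2%. RNA polymerase I machinery had 16.6% ± 7.82 in rRNA genes (SD, n = 7), against 2.36%. All 64 of its peaks in rRNA genes, like all 1969 such peaks of any target, lay in 4 of the 5S rRNA genes, which RNA polymerase III transcribes, and none in the large rRNA genes that RNA polymerase I transcribes. The stretch with these 5S genes had a peak in 76.9% of libraries and in 26 of the 40 enzyme libraries, so short lists have a large share there. Against targets of like peak number, an alternative chosen after seeing the data, the share was 16.6% against 8.48% (two-sided permutation p = 0.00541).

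Mediator had 26.0% ± 7.51 of its peaks in the part of genes next to the coding start (SD, n = 21), against 11.1% for the other targets. RNA polymerase II (22.2%), elongation factors (18.9%) and chromatin remodellers (18.6%) were also higher there by the test, and SAGA passed for no feature. Kinetochore proteins, which attach chromosomes to the spindle, had 51.6% ± 6.13 in intergenic sequence outside promoters (SD, n = 5), against 12.1%. Replication and cohesion proteins had 25.1% ± 17.5 there (SD, n = 21), against 11.9%. Silencing and telomere proteins had 18.4% ± 21.7 within 10000 bp of a chromosome end (SD, n = 8), against 0.375%. Over all classes, 40 pairs of class and feature passed the two-sided permutation test, among them all those named above (adjusted p from 8.47e-05 to 0.0175). The chromosome ends held 0.499% of all peaks on 2.65% of the annotated length, and the enzymes' rRNA gene share of 6.60% ± 5.69 (SD, n = 9 targets, permutation test, adjusted p = 0.0485) was no longer above that of other targets without replicate 1.

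**Figure D2:**
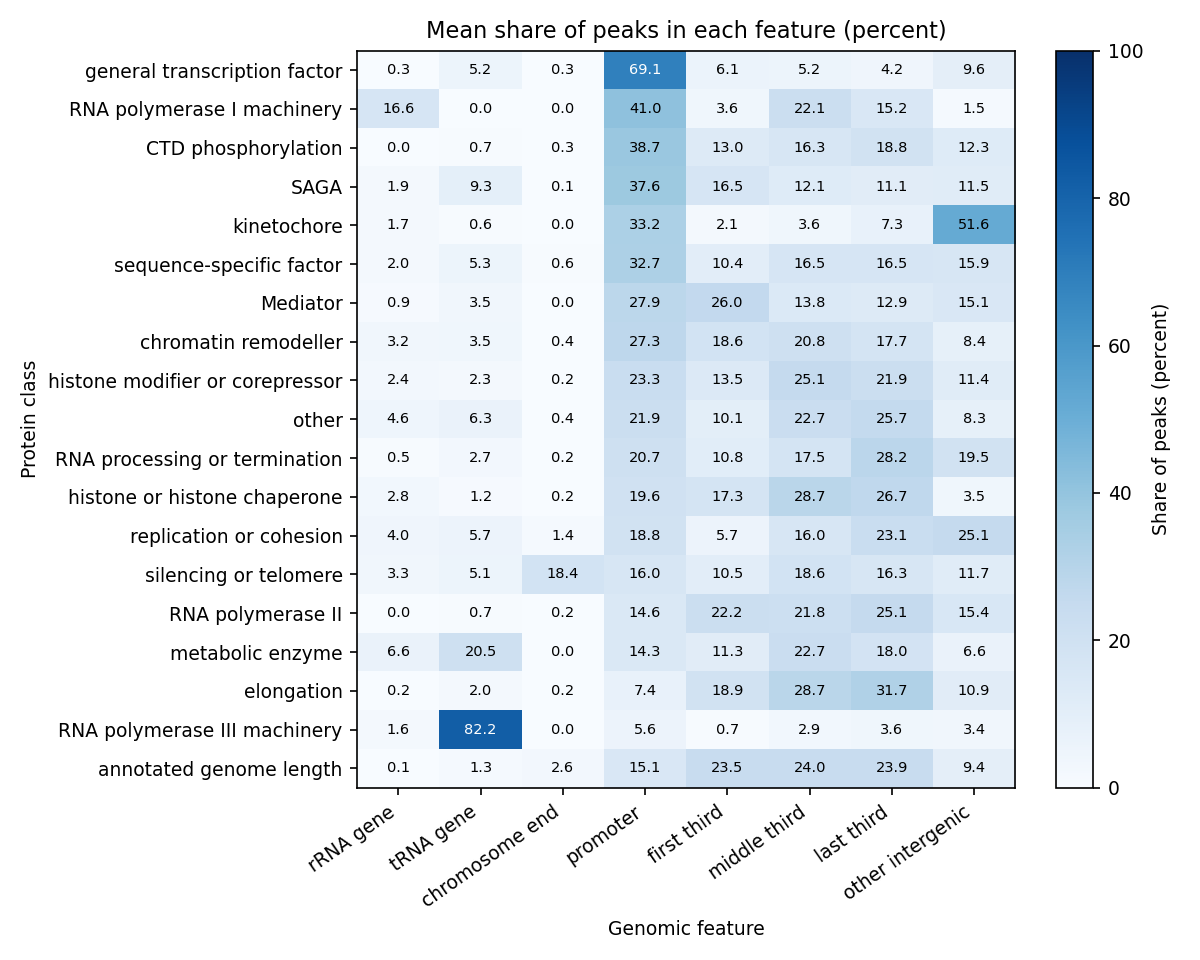
Mean share of peaks (percent, colour scale from 0 to 100) in each genomic feature (columns) for each protein class (rows), with the share of annotated length in the bottom line. RNA polymerase III machinery stands out at tRNA genes (82.2%) and general transcription factors in promoters (69.1%).

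Proteins known to form 1 complex lay at the same places more than proteins with as many peaks. The overlap score runs from 0 to 1. The TFIIIB subunits Bdp1 and Brf1, which recruit RNA polymerase III, scored 0.921, against 0.171 for random pairs matched on peak number. The 6 subunits of TFIIIC, which binds inside tRNA genes, scored 0.796 ± 0.169 (SD over pairs) against 0.141, and 10 RNA polymerase III subunits scored 0.702 ± 0.343 against 0.148. The 5 kinetochore proteins scored 0.693 ± 0.0491 against 0.147, with the centromeric histone Cse4 and Mcm16 as the highest pair at 0.797. TFIIH, which opens promoter DNA, scored 0.617 ± 0.0961 over 9 subunits, and its helicase Ssl2 paired with Tfb4 at 0.782.

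The origin recognition complex scored 0.529 ± 0.118 over 5 subunits, highest for Orc2 with Orc5 (0.718). Condensin, which compacts chromosomes, scored 0.505 ± 0.0806 (Brn1 with Smc4, 0.598). TFIID, which holds the TATA-binding protein, scored 0.448 ± 0.0990 over 14 subunits (Taf11 with Taf13, 0.801), and the silencing proteins Sir2 and Sir4 scored 0.474. Mediator scored 0.369 ± 0.142 over 21 subunits (Pgd1 with Sin4, 0.638). Lower scores above random came from RSC, an essential nucleosome remodeller (0.278, Htl1 with Rsc3 at 0.461), and SAGA (0.243, Taf10 with Taf12 at 0.621). The SAGA set here holds 18 targets, among them Taf10 and Taf12, which were classed as general transcription factors. The acetyltransferase NuA4 (0.227, Eaf3 with Yaf9 at 0.575) and cohesin (0.196, Irr1 with Smc1 at 0.495) also scored low but above random. Of 40 complexes, 33 passed the one-sided permutation test after adjustment. The 7 that did not were CCR4-NOT (adjusted p = 0.271), FACT (0.195), Elongator (0.184), Ino2 with Ino4 (0.0775), INO80 (0.0683), the RNA polymerase I initiation factors (0.0656) and Fhl1 with Ifh1 (0.0573, although their score was 0.60 against 0.207). The 3 targets of FACT scored 0.197 ± 0.290 (SD over pairs), and their highest pair, Pob3 with Spt16, scored 0.532. A complex without a call can thus hold a pair with a high score.

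**Figure D3:**
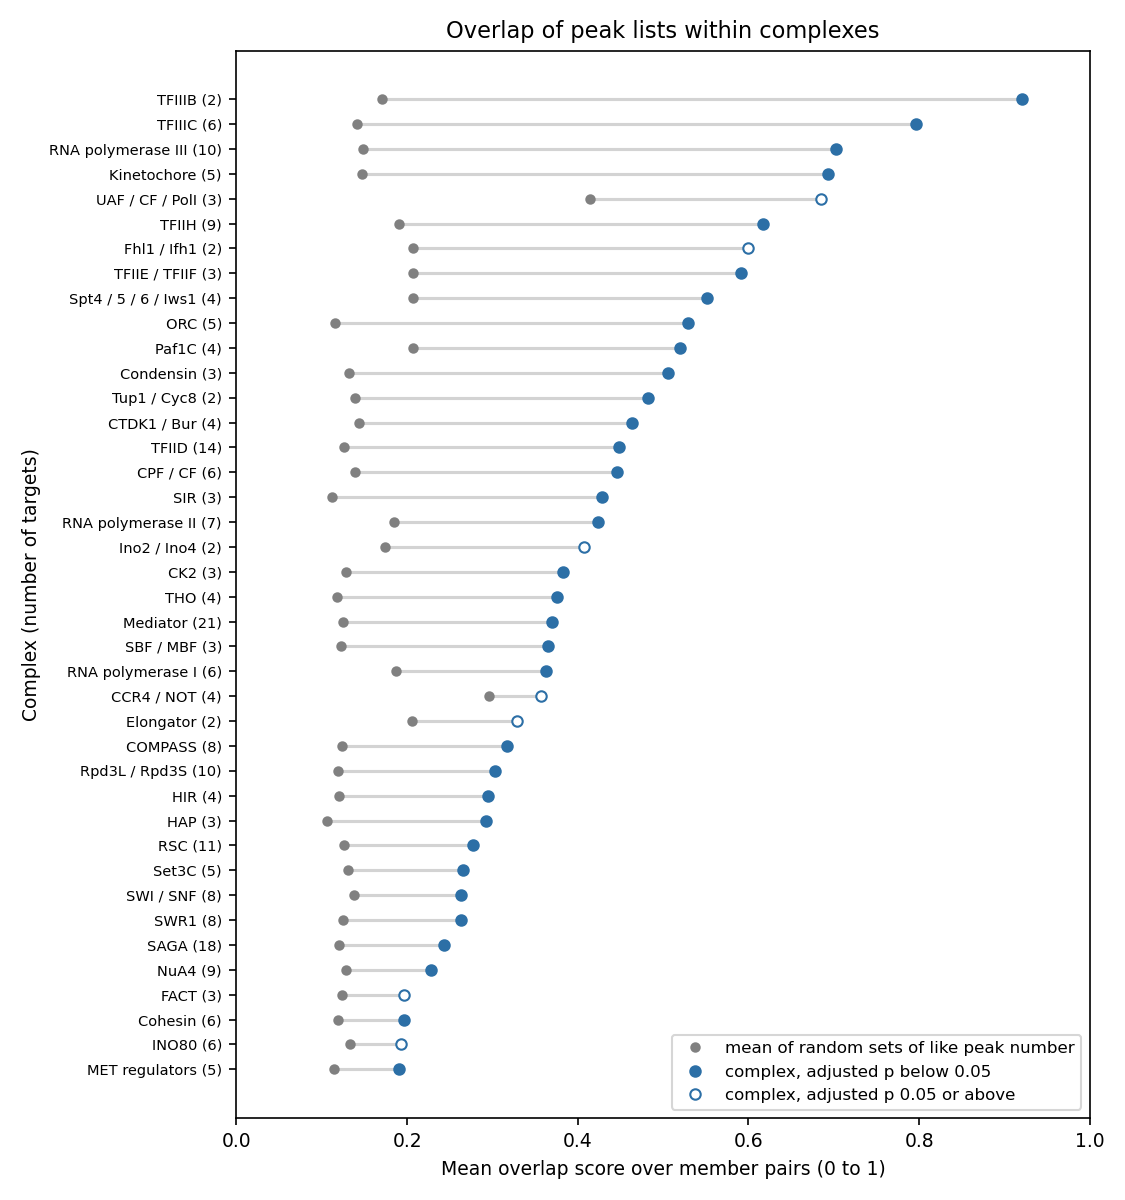
Mean overlap score over member pairs (0 to 1) for each of 40 complexes, with the number of targets in brackets. Grey points are the means of random sets of like peak number, filled points are complexes with an adjusted p below 0.05 and open points the 7 others; TFIIIB lies highest at 0.921.

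Along genes, the classes took up different positions relative to the nearest coding start. Elongation factors had their median peak 325 ± 155 bp downstream (SD, n = 22 targets) and RNA polymerase II subunits 212 ± 43.7 bp downstream (SD, n = 7). RNA processing and termination factors lay 216 ± 261 bp downstream (SD, n = 22). Sequence-specific factors lay upstream, at -158 ± 189 bp (SD, n = 107), RNA polymerase III machinery at -323 ± 27.5 bp (SD, n = 19) and kinetochore proteins at -381 ± 29.7 bp (SD, n = 5). These 6 classes and the class of other proteins passed the two-sided permutation test (adjusted p from 6.00e-05 to 0.0424). RNA polymerase III machinery had 82.2% of its peaks at tRNA genes, and kinetochore proteins 51.6% in intergenic sequence outside promoters. Their distances therefore do not show a position within coding promoters. General transcription factors lay at -97.7 bp with a small spread of 24.8 bp (SD, n = 33), but did not differ from the other targets by the test (adjusted p = 0.122).

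With 5811 Sua7 positions as the reference in place of coding starts, general transcription factors lay at -14.3 ± 13.9 bp (SD, n = 32). Mediator lay at -103 ± 70.5 bp (SD, n = 21, adjusted p = 0.0190) and sequence-specific factors at -78.2 ± 139 bp (SD, n = 107). From coding starts, the main reference, Mediator lay at -37.3 ± 198 bp (SD, n = 21). It did not differ from the other targets there (two-sided permutation test, adjusted p = 0.781). RNA polymerase II lay at 205 ± 17.4 bp (SD, n = 7) and elongation factors at 334 ± 148 bp (SD, n = 22). SAGA lay at -107 ± 73.6 bp (SD, n = 13), which did not pass (adjusted p = 0.0539).

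**Figure D4:**
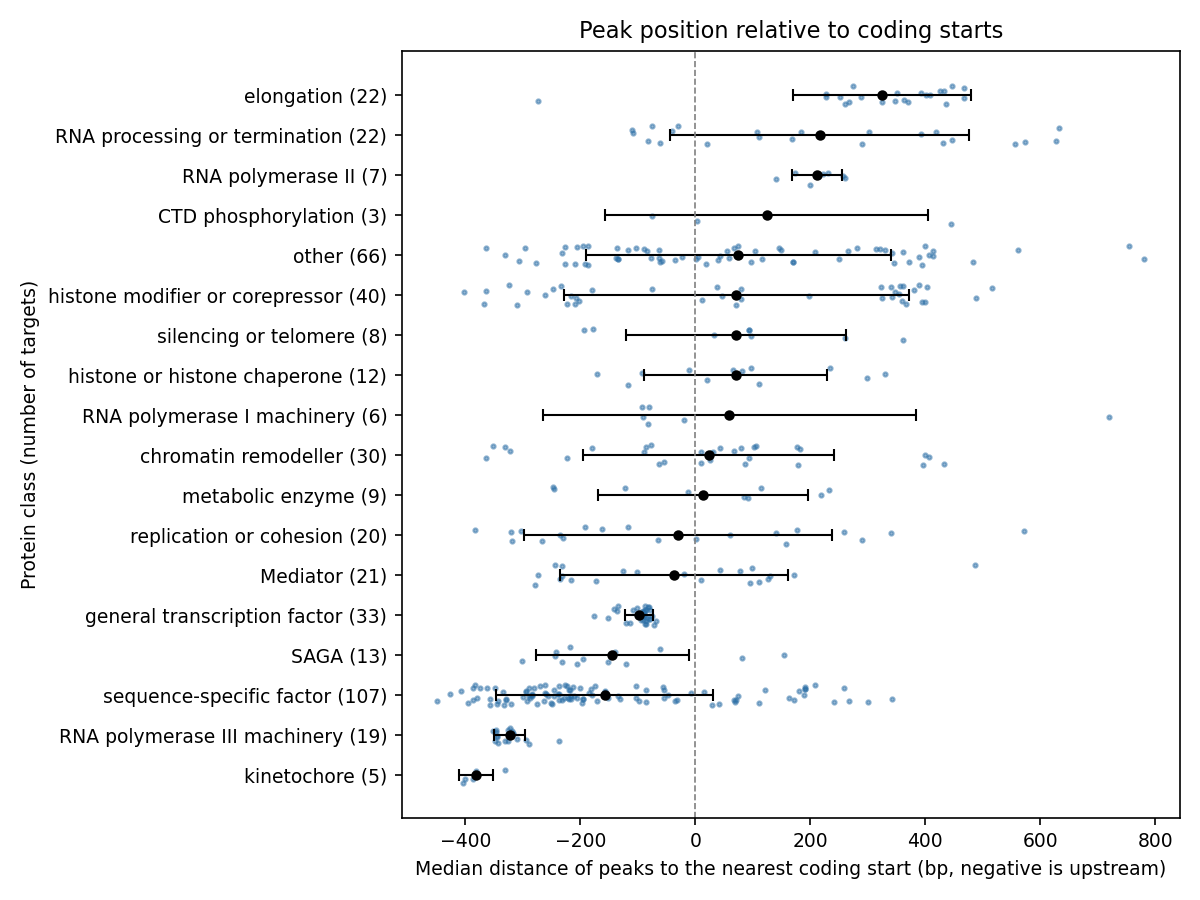
Median distance of peaks from the nearest coding start (bp, negative is upstream) for each target (blue points), by class, with class means and SD in black. General transcription factors cluster at -97.7 bp, while elongation factors average 325 bp.

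Textbook regulators were asked whether they lay at the promoters of genes they are known to control. Bas1, an activator of purine synthesis, had a peak at 14 of 14 known target promoters and at 2.20% of other promoters. Gcr1, an activator of glycolysis, had 14 of 14 (others 2.71%), Lys14, of lysine synthesis, 7 of 7 (others 0.434%), and Mac1, of copper uptake, 5 of 5 (others 2.40%). Among cell cycle regulators, Swi4 lay at 9 of 9 known targets, among them CLN1 and CLN2, Fkh2 at 8 of 8, among them CLB2, and Mcm1 at 9 of 10. Hsf1, the heat shock factor, lay at 22 of 24 without heat shock (others 7.48%).

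The amino acid transporter regulators Stp1 and Stp2 each lay at 7 of 7. The drug resistance regulators Yrr1, Yrm1 and Pdr1 lay at 4 of 4, 3 of 3 and 9 of 10. Hot1, of the osmotic stress response, lay at 3 of 3 and Aro80, of aromatic amino acid breakdown, at ARO9 and ARO10. Cup9 and War1 each lay at the single gene listed for them. At the 138 ribosomal protein promoters, Fhl1 and Ifh1 each lay at 125 and Rap1 at 124. By Fisher's exact test, one-sided, 65 of 89 regulators passed after adjustment and 24 did not. Of the 24, 18 had no known target bound, among them the stress regulators Msn2 and Msn4 and the phosphate regulator Pho4. Msn2, Msn4 and Pho4 had 1 library each, with 35, 40 and 5 peaks, and most of the 18 also had 1 library. With lists that short, a missing peak does not show that the regulator is absent. With a window of 300 bp upstream 43 regulators passed. Of the 65, 12, among them Stp1, Stp2, Hot1, Cup9 and War1, then had no known target bound.

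Ribosomal protein promoters had peaks of many targets, each measured in its own libraries. A ribosomal protein promoter had peaks of 64.6 ± 18.4 distinct targets on average (SD, n = 138 promoters), against 22.6 at all other promoters, and 137 of the 138 lay above the others' median of 14. The 8 histone gene promoters, which form 4 divergent pairs with overlapping windows, had 73.3 ± 7.40 (SD) against 23.5, and the 24 chaperone gene promoters 48.9 ± 34.1 (SD) against 23.4. Subtelomeric COS and PAU genes, repeated families near chromosome ends, had 5.31 ± 5.13 (SD, n = 36) against 23.6. These 4 of 16 lists passed the two-sided permutation test (adjusted p = 0.000160 for ribosomal proteins and 0.0346 for the others). With 1 gene of each divergent pair in the genome, an alternative chosen after seeing the data, only ribosomal proteins passed; the 4 histone promoters left had 72.3 ± 8.77 (SD) against 23.5 (permutation test, adjusted p = 0.0622). The count was 1 with a window of 300 bp upstream and 8 without the enzyme and other classes, and among sequence-specific factors alone the histone promoters were not above the others.

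The 15 promoters with the most targets were of another kind. The first 5 lie at the repeated copper resistance genes CUP1-1 and CUP1-2 on chromosome VIII, led by YHR052C-B with 591 of 716 targets, and CUP1-1 had 584. Beyond these, 7 lie on chromosome XII among the 5S rRNA genes next to the large rRNA genes, led by RRT15 with 527. MUD1 on chromosome II had 337, YLR111W on XII had 253 and YDR010C on IV had 216. A peak in the CUP1 region was listed in 82.3% of libraries and in 32 of the 40 enzyme libraries. No list, heat shock included, had a peak inside the stretch of large rRNA genes from 451786 to 466869 on chromosome XII (sacCer3).

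The targets that favoured ribosomal protein promoters most were subunits of TFIID. Taf13 lay at 134 of the 138 ribosomal protein promoters and at 2.20% of other promoters, and Taf1 at 129 and 1.79%. Taf12, Taf9, Taf10 and Taf8 each lay at 136, Taf6 at 134, TAF7 at 132 and Taf11 at 104. Stb3, a regulator of ribosome synthesis genes, lay at 116 and at 1.5% of the others. By Fisher's exact test, one-sided, 119 of 716 targets passed after adjustment, including 33 of 34 general transcription factors, 7 of 7 RNA polymerase II subunits, 18 of 23 elongation factors and 9 of 13 SAGA targets, but 0 of 24 Mediator targets and 0 of 36 enzymes. The number was 77 when a promoter had to be bound in every library of a target.

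Cofactors were compared over the 5147 promoters with a general transcription factor in at least 2 libraries. SAGA, Mediator or the corepressor Tup1-Cyc8 lay at 744 of these, or 14.5%. Ribosomal protein promoters had a cofactor at 94.2% of 138, with SAGA at 93.5% and Mediator at 1.45%. Histone gene promoters had both SAGA and Mediator at all 8, which are 4 divergent pairs. Chaperone promoters had a cofactor at 81.8% of 22, with Mediator at 50%. The iron regulon (76.9% of 13), glycolysis (66.7% of 15) and hexose transporters (80% of 5, with Tup1-Cyc8 at 60%) also lay above the rest. These 6 of 16 lists passed Fisher's exact test, two-sided (adjusted p from 3.07e-101 to 0.00512), while ribosome biogenesis (4.44% of 45, adjusted p = 0.110) and the proteasome (15.2% of 33, adjusted p = 0.860) did not. With a window of 300 bp upstream 4 lists passed, and hexose transporters (0 of 5) and histone genes (1 of 8) were not among them. With 1 gene of each divergent pair the same 6 lists passed, histone genes with 4 of 4 (Fisher's exact test, adjusted p = 0.00136).

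With heat shock, more chaperone promoters had a peak. Over 15 targets measured with and without it, the mean number of the 24 chaperone promoters with a peak rose by 6.05 ± 5.60 (SD), and was higher for 10 targets (exact sign-flip test, two-sided, p = 0.00195, adjusted p = 0.0176 over 9 tests). Of the 15 targets, 6 are subunits of RSC and 3 of SAGA. They are therefore not independent, which the sign-flip tests with heat shock assume. The SAGA subunit Ubp8 went from 5.67 to 23.5 promoters, Spt7 from 13.3 to 23.5 and Sgf11 from 12 to 21.5. Their promoters with a peak in all went from 121 to 625, 350 to 920 and 362.5 to 397. Within the same library-number series the 3 differences were 11, 8 and 12 at chaperone promoters and 155, 254 and 89 over all promoters. Over 15 targets the difference in all promoters was 185 ± 432 (SD), higher for 10 targets, and was not called (adjusted p = 0.281, exact test). Of the 10 targets higher at chaperone promoters, 7 were also higher over all promoters, while Spt15, Hsf1 and Tpk2 were lower there (differences of -519, -80 and -5, against 10, 6.25 and 2 at chaperone promoters). Rpb3 of RNA polymerase II went from 7.5 to 20 and the TATA-binding protein Spt15 from 12 to 22, both at 3 min. SSA4, an inducible Hsp70 gene, had a peak in 14 of 22 libraries with heat shock and 3 of 32 without. The small heat shock protein genes HSP42 and HSP26 had 13 and 11 of 22 against 3 and 1 of 32, HSP12 had 12 against 2, and CPR6, HSP60, HSP82 and MDJ1 had 13 each against 4, 6, 7 and 8. HSP30 had 9 against 0, and HSP10 had 10 against 4. The call is lost with the 6 min libraries alone (5.25, adjusted p = 0.0703) and with libraries of the same library-number series (5.15, 10 targets, adjusted p = 0.281, exact p = 0.031). As a share of all promoters with a peak, chosen after seeing the data, the difference was 1.68 ± 4.53 points (SD), higher for 7 of 15 targets and without a call (exact test, adjusted p = 0.5). That share would be lower for Ubp8 and Spt7 even with all 24 bound, so for them it decides nothing. Tpk2 had the largest difference in share, 15.4 points, from 2 of 13 promoters with a peak in 1 heat shock library.

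Ribosomal protein promoters gave no call with heat shock. The mean difference over 15 targets was -13 ± 40.5 promoters (SD, adjusted p = 0.321, exact test). All 3 SAGA targets had fewer, although each had more promoters with a peak in all. Sgf11 went from 79 to 2.5 of 138, and Spt15 from 136 to 31. The size of the SAGA differences depended on the libraries used. Over all libraries they were -76.5 for Sgf11, -24.8 for Ubp8 and -59.3 for Spt7. Within the same library-number series they were -36, -78 and -108. Other targets had more, with Rsc9 going from 0 to 60.5, Rpb3 from 39.5 to 59 and Rsc3 from 3.5 to 15.5. Their promoters with a peak in all also rose, from 30.5 to 1437, 753.5 to 907 and 154.5 to 648.5. Within the same series Rsc3 had a difference of 0. For the 3 SAGA targets the mean difference was -53.6 ± 26.3 (SD), where 3 targets cannot give an exact p below 0.25. As a share of all promoters with a peak, chosen after seeing the data, the difference over 15 targets was -4.17 ± 6.89 points (SD). It was higher for 3 of 15, without a call (exact sign-flip test, p = 0.0288, adjusted p = 0.173).

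**Figure D5:**
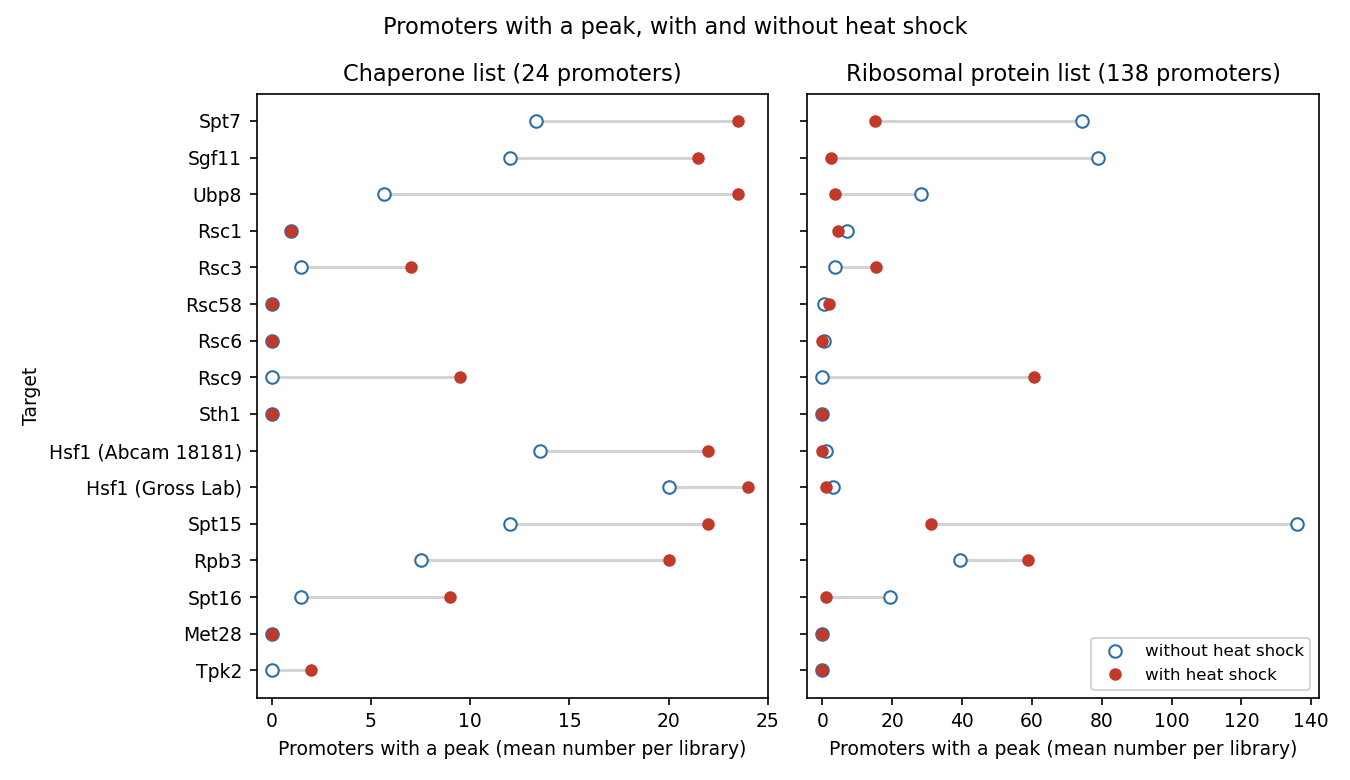
Mean number of promoters with a peak per library for each target, without (open) and with (red) heat shock, in the chaperone list of 24 and the ribosomal protein list of 138. The 3 SAGA targets in the top lines have more chaperone promoters and fewer ribosomal protein promoters with heat shock.

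Peak number with heat shock did not differ by the test. The mean log2 difference was 0.72 ± 2.42 (SD) over 6 subunits of RSC, of which 3 were higher, 1.5 ± 1.32 over 3 SAGA targets, all higher, and 0.36 ± 1.78 over all 15 targets, of which 6 were higher (exact sign-flip test, adjusted p = 0.563 each). Rsc9, from 62.5 ± 23.3 to 1585 ± 183 peaks (SD, n = 2 each), carries the RSC mean, which is -0.071 without it. Among libraries of the same library-number series the means were -0.62 for 5 RSC subunits, 0.73 ± 0.37 (SD) for the 3 SAGA targets, all higher, and -0.19 for 10 targets in all.

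Proteins measured both by their TAP tag and by an antibody to the protein differed in where peaks lay. Over 17 targets, the native antibody's overlap with the TAP libraries was 25.5 ± 24.1 percentage points below that between TAP libraries (a difference of -25.5, SD), lower in 15 (exact sign-flip test, two-sided, p = 0.000122). Spt3, a SAGA subunit that binds the TATA-binding protein, had 12.2% against 90.4%, and the acetyltransferase Gcn5 32.5% against 93.6%. Sua7 had 92.5% against 97.6% and Rap1 97.5% against 94.4%. The native list of Spt3 held 41 peaks, against a TAP mean of 223, and that of Gcn5 held 283 against 130.5. Antibody was not separated from list size or from library-number series. Peak numbers did not differ by the test (log2 -0.61 ± 2.48, SD, 19 targets, 11 lower, exact p = 0.318), and the mean was 0.24 without replicate 1. Taf10, with 1 native peak against a TAP mean of 221, had the lowest value, -7.79, and pulls the mean down. Without replicate 2 only 2 targets had an overlap difference (-15.1 points), too few for a call.

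The 2 histone marks compared by plan lay at different parts of genes. H3K4me3 had its median peak at 14.8% ± 0.0694 of gene length (SD, n = 2), and H3K36me3 at 41.3% ± 0.476 (SD, n = 2). The libraries of H3K4me3 held 5089 and 3887 peaks and those of H3K36me3 held 553 and 23. H3K36me3 lay nearer the start than H3 (52.3% to 53.2% over 3 libraries), H2B (56.2% to 60.5% over 3) and H2BK123ub (45.0% and 47.9%). The label H3 names no mark, so it is not a measure of H3 without marks. H3K9ac lay at 37.4% and 42.6%, H3K27ac at 27.5% and 40.1%, and H4K12ac at 11.3%, from 4 peaks in genes, and 31.1%. An exact permutation test of 2 against 2 libraries gave p = 0.33, the smallest it can give.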

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

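All tests of SAGA against RSC and of library-number series here were chosen only after the results were seen; the test of enzyme peaks was written before. With heat shock, the change in chaperone promoters was 10 larger for 3 SAGA targets (mean 12.5) than for 6 RSC subunits (mean 2.50), with an exact permutation p of 0.0238 over 84 splits (adjusted p = 0.0357 over 6 tests). The subunits of each set belong to 1 complex, so the p-values of SAGA against RSC do not measure spread between complexes. The change in ribosomal protein promoters differed by -65.4 (means -53.6 and 11.8, exact p = 0.0119, adjusted p = 0.0357). Without heat shock the RSC subunits lay at 0 to 7 of the 138 and the SAGA targets at 28.3 to 79, so RSC could hardly fall, and no difference in response is drawn from this value. Within the same library-number series the differences were 10.1 and -74.9 (3 against 5 targets, exact p = 0.0179 each, adjusted p = 0.0357 each). Most RSC subunits had few peaks at these promoters with or without heat shock: Rsc58, Rsc6 and Sth1 had 0 chaperone promoters in both, and the lists of Rsc6 and Sth1 with heat shock held 16 peaks each. List size was not separated from the difference at chaperone promoters. The change in log2 peak number did not differ between the sets by the test (0.79, exact p = 0.631 over all libraries, and 1.35, exact p = 0.196 within the same series).

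A candidate explanation of the higher mean peak number of RSC and SAGA targets with heat shock is that the libraries come from different library-number series. For RSC, the mean within the same library-number series was -0.861 times that over all libraries, but that comparison also loses Rsc9, which has no pair within a series. The 5 subunits left have a mean of -0.071 over all libraries, against 0.72 for the 6, so losing Rsc9 is enough to remove the higher mean. The ratio therefore says nothing about the series. For Rsc9 itself the explanation could not be tested, so it stays open for RSC. For SAGA it was 0.488 times, just under the 0.5 set as the bound, while all 3 targets stayed higher, and 3 targets cannot settle it. A response to heat shock, which the design names, stays open for SAGA.

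The peaks of enzyme libraries may be places recovered whatever protein is tagged. Of 2184 such peaks, 98.4% lay within 100 bp of a peak of another enzyme or of RNA polymerase II or III machinery, places that cover 11.2% of the annotated length. This is consistent with recovery of open or highly transcribed loci. It does not tell the 2 apart, and binding by the enzymes themselves at such loci was not tested.

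The library whose labels name both Abf1 and Mot1 held 1239 peaks that no comparison used. Its overlap scores were 0.365 and 0.414 with the Abf1 libraries and 0.425 with the Mot1 library, and its highest were 0.534 with a Taf5 library and 0.530 with an Ncb2 library.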

How the results depend on the processing

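The alternatives without Rsc9, with 1 library-number series, with a share of promoters, with targets of like peak number and with 1 gene of each divergent pair were chosen after seeing the data, the others before. Apart from the values given here, results kept direction and side of the threshold in 599 settings of main results and 590 of named items. Named items kept direction but lost their call in 104. Most of the 599 settings leave 1 library out of a heat shock result, with 42 such settings for each. Of these results only chaperone promoters over all targets had a call to lose, so the count does not measure robustness. The cause of changes was not tested unless stated. Complexes past the threshold ranged from 31 to 37, class and feature pairs from 29 to 41, and replicate overlap from 60.0% to 94.3%.

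For peak number, classes past the threshold were 16, and 10 against all other targets, where the class difference (log10) was -0.0740 for chromatin remodellers, -0.241 for histones and their chaperones, -0.00907 for kinetochore and -0.667 for other proteins. They ranged from 0 to 16 without replicate 1 or 2; without replicate 1 only 4 enzymes remain, and histones and their chaperones ranged from -0.000906 to 0.522. With a replicate block 12 passed; replicate numbers are not known to pair libraries, and replicate 1 exceeded replicate 2 by 0.120 (log10, 366 groups). Centring library-number batches gave 14.

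Classes that differed in replicate overlap were 5 with a 50 bp match, 2 with 250 bp and 5 with at least 5 peaks. Feature shares that turned were other proteins in promoters with at least 5 peaks (1.27 points) and, without replicate 1, enzymes and other proteins in rRNA genes (-0.346 to 4.67 and -0.231 to 2.66 points without replicate 1 and 2).

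With 300 bp upstream, 43 regulators passed, and known minus other share was -0.850 for War1, -0.267 for Hot1, -0.717 for Stp1, -1.62 for Stp2 and -0.433 for Cup9; 12 of the 65 turned, all with 0 known targets bound. Bound in every library, Cup9 was at -0.733 and 4 of the 65 turned, also with 0. Promoter lists past the threshold were 1 with 300 bp, 1 with 1 gene of each divergent pair and 8 without enzyme and other classes; hexose transporters turned to -7.50 points for cofactors with 300 bp (0 of 5, adjusted p = 1), and histone promoters to -1.01 for sequence-specific factors only. Targets at ribosomal protein promoters were 77 when bound in every library.

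Heat shock at chaperone promoters was 5.25 at 6 min, 5.15 within the same library-number series, and 1.68 points as a share of all promoters with a peak (void for Ubp8 and Spt7, whose share would be lower with all 24 bound), all without a call (adjusted p over the alternatives 0.0176 to 0.5); leaving out each library gave 5.58 to 6.52. Peak number turned to -0.62 for RSC and -0.19 over all targets within the same series, and to -0.071 for RSC without Rsc9. Leaving out 1 library gave 0.28 to 1.60 for RSC. The native antibody difference ranged from -0.63 to 0.24 (log2) without replicate 2 or 1; for overlap, without replicate 2 it was -15.1 over 2 targets, too few for a call, and without replicate 1 a single target was left. The motif alternatives were not run. Read depth is unknown and limits all lists: missing peaks are not shown absent.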

Other observations

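The tests in this part on the tagged locus were written before the result was seen; the descriptions of shared places were chosen after. At least 4 of the 5 kinetochore proteins shared a peak at 18 places, with at least 1 on each of the 16 chromosomes. On chromosome VIII, 2 of its 3 places lay at the CUP1 genes, where 609 and 575 targets had a peak. At the other 16 places, 1 per chromosome, from 22 to 178 targets had a peak. The condensin subunits Brn1, Smc4 and Ycs4, the cohesin subunit Smc3 and its loader Scc2 had a peak at all 16, as did the cyclin Cln1, with 57 peaks in all. Cbf1, a DNA-binding protein of centromeres and methionine genes, lay at 15, and so did Spt21, Fun30, Fzf1 and Yox1.

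At least 4 of the 5 origin recognition complex subunits shared a peak at 165 places. Of the 152 places that were neither near a tRNA gene nor held by most targets, Cdc46, a subunit of the replicative helicase, had a peak at 151. The forkhead factor Fkh1 lay at 60, the histone variant Htz1 at 55 and the silencing protein Sir3 at 23. Transcription and RNA processing proteins with many peaks lay at more of them than Sir3 did: Sua7 at 41, Tfa2 at 35, Rna14 at 34, Pcf11 and Ssl2 at 32 each, Ref2 at 25 and Tfb4 at 24.

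Tagged libraries may recover the tagged gene itself. Of 1035 TAP libraries, 111 had a peak inside or within 500 bp of the gene they tag, or 10.7%, against 4.06% of other TAP libraries at the same genes, a ratio of 2.64. A ratio above 1 is what recovery of the tagged locus in its own library would give. However, none of the own libraries of the 36 metabolic enzymes had such a peak. For the enzymes this argues against recovery of the tagged locus, but their lists are short, with a median of 9.5 peaks per target. Targets with a peak at their own gene included the DNA-binding proteins Rap1, Reb1 and Swi4 and the transcription proteins Rpb3 and Spt5. Of the 111 libraries, 44 had a peak in the 500 bp after the gene. Rpb3 and Spt5 had one there in 2 of 2 libraries each, and Rap1, Reb1 and Swi4 in 0 of 2 each. For targets other than enzymes, binding of a protein to its own gene was not separated from recovery of the tagged locus.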
